A study of Sterkiella histriomuscorum with 4 samples.

How the data were processed

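Cells of Oxytricha trifallax strains JRB310 and JRB510 were mated and crosslinked with 1% formaldehyde, per the labels' protocols. RNA bound to Otiwi1 was recovered with an antibody and made into small RNA libraries with a TruSeq kit and a barcode per sample. There was 1 library at each of 12, 19, 23 and 30 hr after mixing, and groups were taken from the sample titles.

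The deposited files list alignments, 1 per line, without a header. Per the authors' accompanying text, reads were trimmed of adapters, aligned with SHRiMP 2.1.0 in its gmapper program, and alignments with more than 2 mismatches were removed. That text also gives the order of the columns, which hold the read name, reference name, strand, start and end on the reference and in the read, read length, score, edit string and read sequence. The score is the alignment score of SHRiMP as deposited by the authors, and it was not used in any result. The number of copies of each sequence was read from the end of the read name. The text does not explain this number, but it never increased down a file, and each serial number had 1 sequence. The name of the trimmed read set includes the letters teloRM, which the sources used here do not explain. It stays open whether telomeric reads were removed before alignment. The genome build, the reference lengths and any gene annotation are not given in the sources used here.

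Depth was the number of aligned reads in each listing, which ranged from 20050160 at 23 hr to 35177095 at 30 hr. From gaps in the serial numbers, listed reads were 87.7% to 90.4% of all reads numbered up to the last listed one. Reads with a single listed alignment were 88.0% to 88.1% of listed reads. Each read counted once in shares of lengths and 5' bases, and in counts per reference sequence it was divided equally over its listed alignments. Reference classes were taken from names alone. Names beginning with chromosome or scaffold, whose organism is not stated, were kept out of the contigs.

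Lengths and 5' bases are shares of reads with exact Clopper-Pearson 95% intervals, and a count of 0 was given an upper limit of 3 reads. Shared sequences between 2 libraries are the distinct 27-nt sequences found in both, counted in each library, as a share of the sum of the distinct sequences of both. For this, libraries were thinned to the smallest number of 27-nt reads with a fixed seed. Changes of reference sequences are log2 ratios of RPM of 27-nt reads with a pseudocount of 0.5 reads, for those with at least 200 reads over both libraries, with exact conditional intervals of the ratio. A change of at least 2-fold is a rule of size and no test. Strand balance used contigs with at least 200 reads. Density along contigs used contigs with a mapped extent of at least 500 bases, in 20 equal parts and within 100 bases of the ends. The mapped extent ran from base 1 to the last base with an alignment in any library. Overlaps were counted between occupied 5' ends of 27-nt reads aligned once, in full and without mismatch. Pairs were counted at each 5'-to-5' overlap, and the z score used the other overlaps from 1 to 27 nt. Mismatches were read from the edit strings. None were listed at read positions 1, 2, 26 and 27, where the alignments were shortened instead.

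Reference sequences were named by a rule. It took the 10 with the highest mean RPM, the 5 largest rises and 5 largest falls of each consecutive comparison by the interval bound nearest to no change, and the 3 most abundant sequences of each library. The rises and falls from 12 to 30 hr were ranked in the same way, although the rule did not name that comparison, and they count among the single reference sequences under other settings. As the files pair no identifiers with genes, at most 2 identifiers that rose and 2 that fell are printed, and the others are summarised. The rule, the measures and most alternatives were fixed before the data were examined.

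The calculations were tested on simulated data. In each of the 4 comparisons of contigs, Poisson counts were drawn for the real reference sequences with 100 changed 3-fold and 100 changed 4-fold. All 100 of either size were recovered in each comparison, and 0 of the 21055 unchanged ones of 23 against 19 hr passed 2-fold, as did 0 of 21250 for 19 against 12 hr, 0 of 21149 for 30 against 23 hr and 0 of 21339 for 30 against 12 hr. These draws held counting error and no variation between libraries. A simulated excess of pairs at 25 nt was found at 25 nt. Scripts used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

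Alternatives counted distinct sequences, reads with a single alignment, alignments without mismatch, other lengths, other minimum counts, another pseudocount and a median-of-ratios scaling. Raw reads, a reference genome and libraries of total small RNA were not used here.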

Results

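Small RNAs bound by Otiwi1, a Piwi protein of the ciliate Oxytricha trifallax (the same organism as Sterkiella histriomuscorum), were sequenced at 4 times after mating strains JRB310 and JRB510 were mixed. Piwi proteins carry small RNAs that guide the recognition of nucleic acids, and conjugating ciliates rebuild their somatic genome from a copy of the germline genome. The question was which RNAs Otiwi1 held as cells passed from pairing to exconjugants, the cells left after pairs separate. By the labels, 90% of cells were in pairs at 12 hr, 90% were early exconjugants at 19 hr, 80% were early exconjugants at 23 hr and 90% were late exconjugants at 30 hr. Each time point had 1 library, and levels are given as RPM, reads scaled to a library of 1000000 reads of 27 nt, unless another class or all listed reads are named. Differences between times therefore had no replicate check, and no test between times was made. The files listed 34747355 aligned reads at 12 hr, 31677181 at 19 hr, 20050160 at 23 hr and 35177095 at 30 hr. Intervals given below are exact 95% Clopper-Pearson intervals or exact intervals of a ratio of counts. They cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

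Otiwi1 held almost a single length of RNA at every stage. Reads of 27 nt made up 88.8% of listed reads at 12 hr (interval 88.79 to 88.82), 88.5% at 19 hr (88.52 to 88.54), 87.9% at 23 hr (87.87 to 87.90) and 87.8% at 30 hr (87.82 to 87.84). The neighbouring lengths came next, with 2.96% to 3.65% of reads at 26 nt and 3.28% to 4.24% at 28 nt. A smaller class lay around 22 nt, which held 1.18% of reads at 12 hr, 0.780% at 19 hr, 0.853% at 23 hr and 0.911% at 30 hr. Counted as distinct sequences, 27-nt RNAs made up 75.3% to 79.3% of each library. No sequence dominated, as the 10 most abundant together took 0.0314% to 0.0384% of reads.

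**Figure D1:**
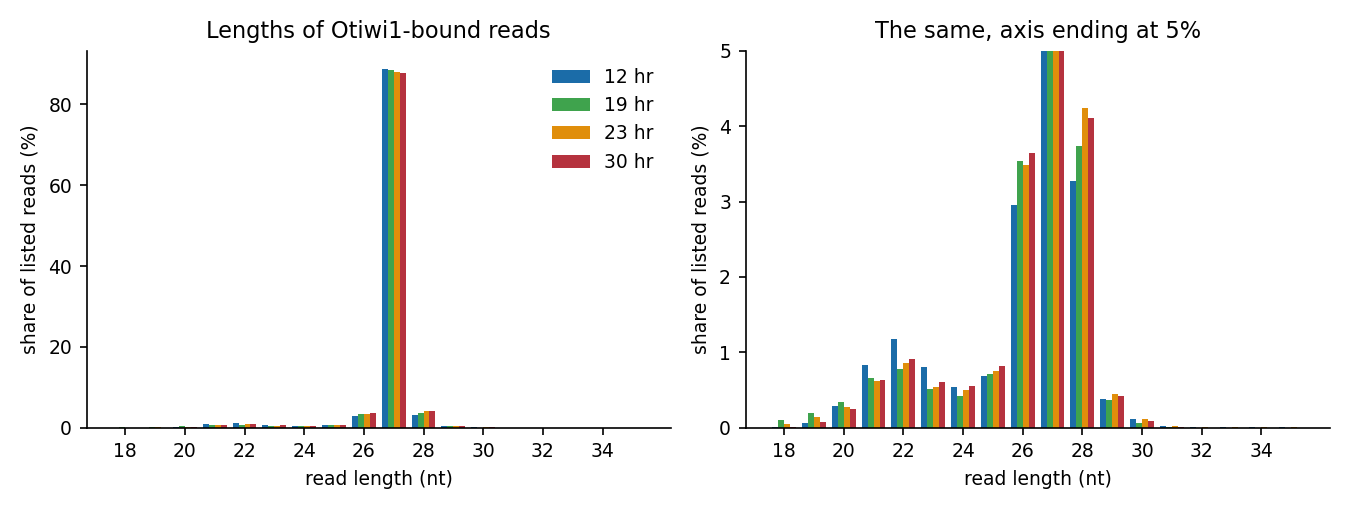
Share of listed reads (%, vertical axis) by read length (nt, horizontal axis) for the 4 libraries, with the right panel showing the same bars on an axis that ends at 5%, where the 27-nt bars run off the top. The 27-nt bars reach 88.8% at 12 hr, 88.5% at 19 hr, 87.9% at 23 hr and 87.8% at 30 hr, and a low second class sits at 22 nt.

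The 27-nt RNAs started with U at all stages. The share with a 5' U was 98.7% at 12 hr, 98.5% at 19 hr, 98.3% at 23 hr and 98.1% at 30 hr, with exact intervals narrower than the last digit given. In step, the share with a 5' A went from 0.674% at 12 hr to 0.999% at 30 hr and that with a 5' C from 0.537% to 0.868%. The 22-nt class started with U less often, in 86.7% of its reads at 12 hr, 88.2% at 19 hr, 88.5% at 23 hr and 87.4% at 30 hr. An A at position 10, the mark of ping-pong amplification in animals, stood at 35.9% at 12 hr, 35.3% at 19 hr, 34.9% at 23 hr and 35.2% at 30 hr, against 33.6% to 34.8% at positions 9 and 11. Position 10 did not stand out, as position 18 had 35.9%, 35.5%, 34.9% and 35.1% A at the successive times. Position 25 had more A, with 39.5% to 40.7% over the 4 libraries, and position 26 had 20.6% to 22.9%.

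The 27-nt RNAs came from nearly all contigs that appear in the listings. Of 22393 numbered contigs with any listed alignment, 22292 had a 27-nt read at 12 hr, 22343 at 19 hr, 22333 at 23 hr and 22368 at 30 hr. Contigs without any alignment are not listed, so the share of the whole reference is not known here. Reads covered 89.9%, 86.7%, 83.5% and 90.6% of the mapped extent of these contigs at the successive times, and the lowest value belonged to the library with the fewest reads. Read density had a median over contigs of 12.5 RPM per kb at 12 hr and 13.7 at 30 hr, and a 5th to 95th percentile range of 3.33 to 29.3 at 12 hr. The 100 most abundant contigs together held 3.93% to 4.97% of 27-nt reads. Contig16677.0, with the most reads, had a mean of 969 RPM over the 4 libraries but a mapped extent of 65927 bases, so that its density was 14.7 RPM per kb. The 9 contigs ranked after it averaged 614 to 757 RPM. The files pair no contig with a gene name, and no gene is named here.

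Both strands were represented nearly equally. The median contig with at least 200 reads had 50.3% of its 27-nt reads on the listed plus strand at 12 hr, 50.2% at 19 hr, 50.2% at 23 hr and 50.1% at 30 hr. Whichever strand of a contig had more reads held a median of 54.6% at 12 hr, 55.1% at 19 hr, 55.2% at 23 hr and 55.4% at 30 hr. At least 90% of reads lay on 1 strand in 0 of 20057 contigs at 12 hr, 1 of 20301 at 19 hr, 5 of 18683 at 23 hr and 5 of 20616 at 30 hr. Reads thinned out towards contig ends. Within 100 bases of the ends, density was 0.304 of the interior at 12 hr, 0.291 at 19 hr, 0.261 at 23 hr and 0.295 at 30 hr. Contig lengths are not in the files used here, so the end was taken as the last base with any alignment, and the value at the listed start (0.174 at 12 hr) is not comparable with that at the end (0.434). None of the listed reads held the telomeric repeat, which limits such reads in the listings to at most 0.0863 RPM at 12 hr, 0.0947 at 19 hr, 0.150 at 23 hr and 0.0853 at 30 hr, scaled to all listed reads. Whether telomeric reads were removed before alignment stays open. If they were, the count of 0 was fixed in advance and sets no limit on telomeric RNAs bound by Otiwi1.

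Reads on opposite strands met most often at an overlap of 25 nt between their 5' ends, not at the 10 nt of ping-pong pairs. At 12 hr, 368281 pairs of occupied positions overlapped by 25 nt, 1.60 times the median of the other overlaps from 1 to 27 nt (z score 3.36). The ratio was 1.51 at 19 hr, 1.77 at 23 hr and 1.66 at 30 hr, with z scores of 2.84, 4.06 and 3.66. The other overlaps included that of 1 nt, which was nearly empty, with 22480 pairs at 12 hr, 0.097 times the median. It widened the spread behind the z scores and so lowered them. At 10 nt the ratios were 1.06, 1.04, 1.06 and 1.05. An overlap of 25 nt between 27-nt reads leaves 2 unpaired bases at each 3' end.

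**Figure D2:**
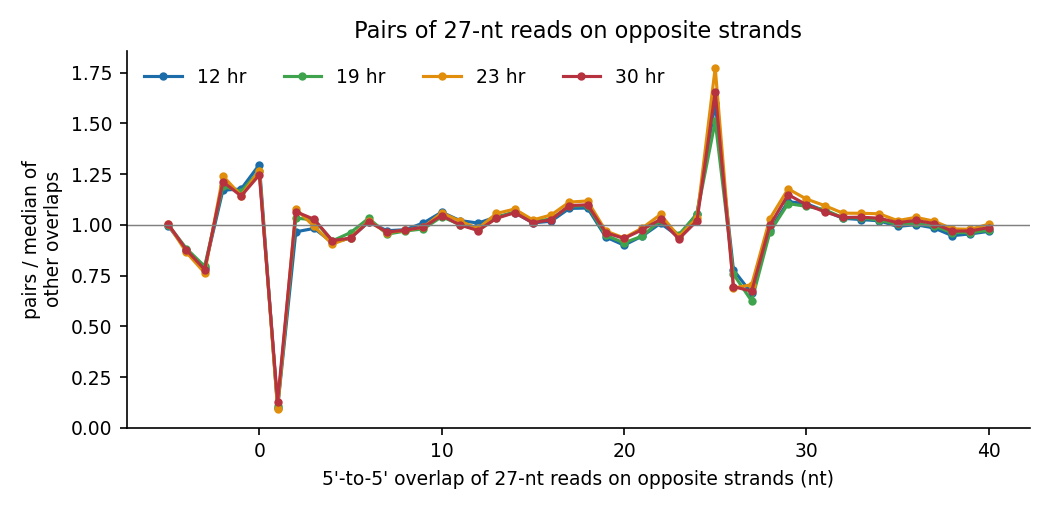
Pairs of occupied 5' ends of 27-nt reads on opposite strands at each overlap, divided by the median of the other overlaps from 1 to 27 nt (vertical axis), against the 5'-to-5' overlap in nt (horizontal axis, values of 0 and below are reads that do not overlap), 1 line per library. All 4 lines peak at 25 nt, at 1.51 to 1.77, and stay between 1.04 and 1.06 at 10 nt.

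Other named reference sequences took few reads after division over alignments, and the transposon sequence changed most among them. TBE transposons are germline elements removed when the somatic genome is rebuilt. With each read divided over its alignments, 27-nt reads on the TBE sequence stood at 0.130 RPM at 12 hr (interval 0.0353 to 0.332), 1.88 at 19 hr (1.41 to 2.46), 3.12 at 23 hr (2.35 to 4.06) and 7.27 at 30 hr (6.35 to 8.29). The ratio of 30 to 12 hr was 56.1, with an interval of 21.6 to 208 that rests on 4 reads at 12 hr. With reads of every length it was 6.65, since other lengths were already present at 12 hr, and with reads of a single alignment it was 164, which rests on 1 read at 12 hr. Counted whole, 170 of the 195 TBE reads at 12 hr were 22 nt long, and 163 of these started with U. Later, 37 of 82 such 22-nt reads at 19 hr, 42 of 85 at 23 hr and 95 of 171 at 30 hr did. Reads of 27 nt made up 7 of 195 at 12 hr, 65 of 737 at 19 hr, 71 of 711 at 23 hr and 292 of 1413 at 30 hr. Their share with a 5' U was 46.2% at 19 hr (interval 33.7 to 59.0), 36.6% at 23 hr (25.5 to 48.9) and 67.8% at 30 hr (62.1 to 73.1), below the 98% of all 27-nt reads, and all 7 at 12 hr started with U. TBE reads had no peak at 27 nt at 19 and 23 hr. Their highest count was then at 22 nt, and 62 and 67 reads were 26 nt long. At 30 hr 27 nt was the peak, against 131 reads of 26 nt and 123 of 28 nt.

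**Figure D3:**
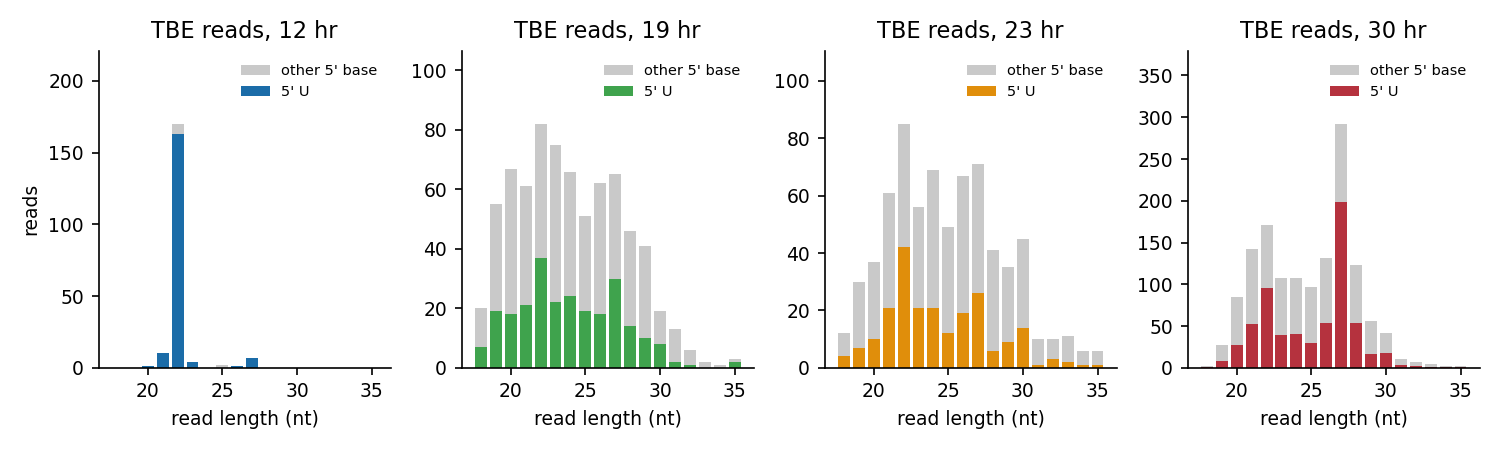
Number of reads listed on the TBE transposon sequence (vertical axis, a separate scale in each panel) by read length in nt (horizontal axis) at 12, 19, 23 and 30 hr, with reads that start with U in colour and all others in grey. At 12 hr 170 of 195 reads were 22 nt long. At 19 and 23 hr the reads spread over many lengths, with the highest bar at 22 nt (82 and 85 reads). At 30 hr the highest bar is at 27 nt, with 292 reads, 198 of them with a 5' U.

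Mitochondrial 27-nt reads stayed low, at 4.20 RPM at 12 hr, 2.01 at 19 hr, 2.67 at 23 hr and 3.48 at 30 hr. A reference sequence named only by an identifier took 230, 213, 201 and 179 RPM among 27-nt reads at these times. Of the reads of any length listed on it, 99.7% to 99.8% were also listed on contigs. Its levels here and below are thus only the part left after division over alignments, and fewer than the reads listed on it. All reads carrying a conserved motif of small-subunit ribosomal RNA were listed on it at 12, 19 and 23 hr (17, 11 and 15 reads), and 37 of 38 were at 30 hr. Among reads of 18 to 25 nt its level was higher, with 4871, 4579, 8501 and 9507 RPM among them at the successive times. Mitochondrial reads of these lengths stood at 1452, 406, 489 and 755 RPM. The most abundant single sequence at 19, 23 and 30 hr was the 21-nt TCGAATCTCAGTAGAGCTACC, listed at bases 5772 to 5790 of the plus strand of Contig21948.0, with 39.6 RPM at 12 hr and 122, 133 and 137 later, here scaled to all listed reads. The genome build is not given in the sources used here, and positions are those of the files.

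Many of the same 27-nt RNAs recurred from stage to stage. With every library thinned to 17621707 reads of 27 nt, 47.6% of distinct sequences were shared between 12 and 19 hr, and 40.8% to 42.0% between any other pair. Depth limited these shares. Disjoint draws of 8810853 reads from 1 library shared 42.1% at 12 hr, 43.4% at 19 hr, 35.97% at 23 hr and 35.5% at 30 hr, while draws of this size shared 41.3% between 12 and 19 hr, 35.1% between 23 and 30 hr and 35.2% to 36.4% between the other pairs. RPM values of reference sequences also followed each other closely. Across 21905 reference sequences with at least 200 reads, Pearson's r of log2 RPM was 0.987 between 12 and 19 hr, 0.988 between 19 and 23 hr, 0.995 between 23 and 30 hr and 0.979 between 12 and 30 hr (Spearman's rho 0.987, 0.989, 0.996 and 0.980). The lowest of the 6 values was 0.976, between 12 and 23 hr. Reference sequences are not independent replicates, and no p-value was computed.

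Few reference sequences changed at least 2-fold between consecutive stages. From 12 to 19 hr, 6 of 21452 with at least 200 reads were at least 2-fold higher and 0 were at least 2-fold lower. From 19 to 23 hr, 20 of 21253 were higher and 24 lower, and the exact interval lay beyond 2-fold for 6 and 14 of them. From 23 to 30 hr, 2 of 21357 were higher and 0 lower, and these 2 were the TBE sequence and Contig4305.0. With reads of every length neither reached 2-fold, at log2 ratios of 0.16 and 0.30. Over the whole course, from 12 to 30 hr, 125 of 21534 were higher and 12 lower, with intervals beyond 2-fold for 35 and 7. Within 1.5-fold lay 97.2%, 98.6% and 99.9% of reference sequences in the 3 consecutive comparisons and 93.2% from 12 to 30 hr. The counts depended on the setting. With each distinct sequence counted once, 0 were at least 2-fold higher from 12 to 19 hr, 0 from 19 to 23 hr, 2 from 23 to 30 hr and 1 from 12 to 30 hr, while 18 were lower from 19 to 23 hr and 5 from 12 to 30 hr. Scaled by the median of ratios, 2 were higher from 12 to 19 hr, and 81 were higher and 18 lower from 12 to 30 hr. Other settings raised the counts from 19 to 23 hr, to 33 higher and 66 lower with reads of a single alignment, and to 23 and 57 without mismatch.

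Among reference sequences with at least 200 reads over the pair, the largest log2 ratios between consecutive times came from 19 to 23 hr. The TBE sequence was below this minimum from 12 to 19 hr. Contig9057.0 had 36.3 RPM at 19 hr and 8.99 at 23 hr, a log2 ratio of -2.01 (interval -2.27 to -1.77), and 14.1 at 30 hr. Contig17834.0 had 34.4 and 9.25, a log2 ratio of -1.89 (-2.14 to -1.65). Contig17968.0 had 10.8 at 19 hr and 39.4 at 23 hr, a log2 ratio of 1.86 (1.67 to 2.06). With reads of a single alignment this was 0.49 and with distinct sequences 0.33, both under 2-fold. Its rise rested largely on the 27-nt sequence CTCGGGAAACCTTCGTGCTGATAGCTT, which had 170 reads at 19 hr, 948 at 23 hr and 1525 at 30 hr, each divided over 2 alignments. The other contigs that the naming rule took for this step had log2 ratios of 1.22 to 1.64 upwards and -2.05 to -1.65 downwards. The one at 1.64, on which the same sequence is listed, had 0.67 with reads of a single alignment, and with distinct sequences these other rises were 0.59 to 0.83, all under 2-fold. The 24 contigs that were lower at 23 hr had a median log2 ratio of 0.12 from 12 to 19 hr and 0.50 from 23 to 30 hr, and the 20 that were higher had 0.10 and -0.17. From 23 to 30 hr, Contig4305.0 went from 2.35 to 6.47 RPM, a log2 ratio of 1.45 (0.99 to 1.998).

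**Figure D4:**
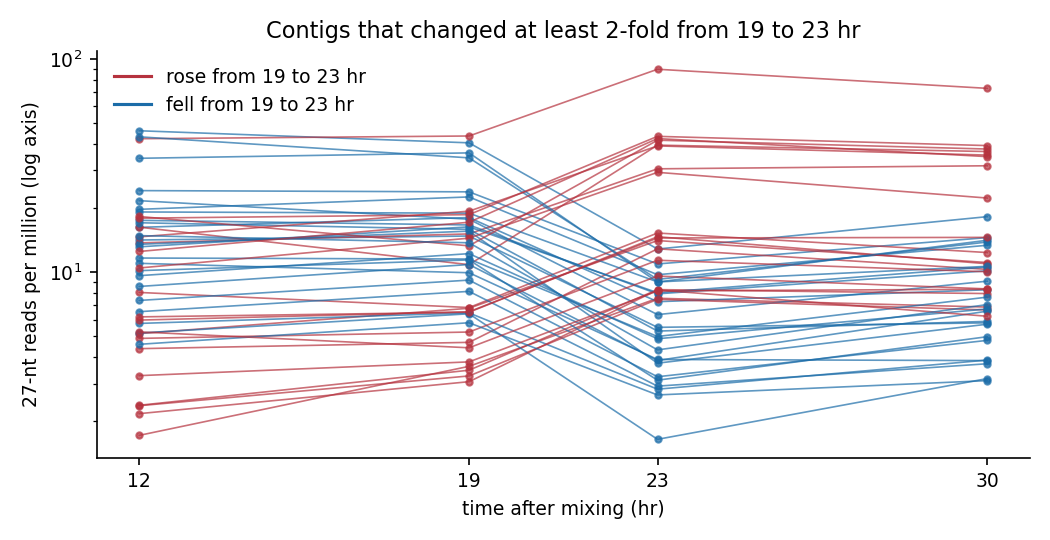
RPM of 27-nt reads (vertical log axis) against hours after mixing (horizontal axis), 1 line for each of the 44 contigs that differed at least 2-fold between 19 and 23 hr. From 12 to 19 hr the 20 higher at 23 hr (red) had a median log2 ratio of 0.10 and the 24 lower (blue) 0.12, with single contigs moving either way, and from 23 to 30 hr the lower ones had a median of 0.50.

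The step from 19 to 23 hr also separated the libraries in their mismatches to the reference. A mismatch to the reference was listed for 20.6% of 27-nt reads at 12 hr, 22.4% at 19 hr, 28.4% at 23 hr and 28.1% at 30 hr. Read position 4 alone held the only mismatch of 0.642%, 0.713%, 5.61% and 5.61% of reads. Positions 7 and 13 were also higher at 23 and 30 hr, and positions 3, 11 and 23 were higher at 12 and 19 hr. Comparisons across 19 and 23 hr, including that of 12 with 30 hr, therefore set libraries with different mismatch profiles against each other, and time and this split cannot be told apart for them.

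**Figure D5:**
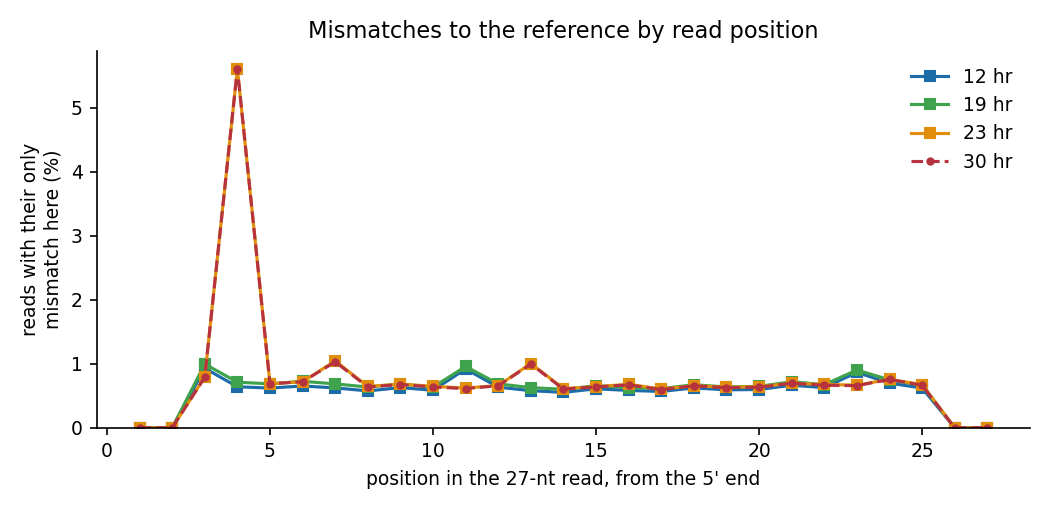
Share of 27-nt reads whose only mismatch to the reference lies at a given read position (%, vertical axis), against the position counted from the 5' end (horizontal axis), 1 line per library. The lines of 23 and 30 hr lie on each other and reach 5.61% at position 4, where those of 12 and 19 hr are at 0.642% and 0.713%.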

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

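Values in this part are signals in reads that lay mostly outside the 27-nt reads of contigs. Without control libraries, they are set against the limit that a count of 0 allows, which shows only that such reads were present.

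Reads of 21 to 23 nt made up 2.82% of reads at 12 hr, 1.95% at 19 hr, 2.02% at 23 hr and 2.15% at 30 hr, where a count of 0 would allow 8.63e-06%, 9.47e-06%, 1.50e-05% and 8.53e-06%. Of the plus-strand positions where a 22-nt read started, 49.3% at 12 hr, 51.6% at 19 hr, 42.6% at 23 hr and 48.0% at 30 hr were also the start of a 27-nt read, against 11.5%, 10.7%, 8.28% and 10.7% of positions 12 bases upstream. The upstream positions were not restricted to U, the first base of most reads of both lengths. How much of this difference the shared 5' U gives by itself was not measured. At 12 hr, 134 of 20191 contigs held at least 8-fold more of the 21-to-23-nt reads than their share of 27-nt reads, compared with 9 of 20357 at 19 hr, 26 of 18792 at 23 hr and 44 of 20684 at 30 hr. These contigs held 3.94%, 1.70%, 2.67% and 3.28% of the 21-to-23-nt reads of their libraries.

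Reads listed on numbered chromosomes and scaffolds, and on no contig, stood at 55.4 RPM at 12 hr, 67.2 at 19 hr, 70.6 at 23 hr and 59.9 at 30 hr, scaled to all listed reads, where a count of 0 would allow 0.0863, 0.0947, 0.150 and 0.0853. Without those of 27 nt, they stood at 51.8, 65.3, 67.9 and 56.4 RPM. Their 27-nt reads were counted in the comparisons of reference sequences, though not among contigs. The files do not say which organism these references belong to, and the source of the reads was not determined.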

How the results depend on the processing

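The choices with alignments without mismatch for 5' U, contigs, TBE and shared sequences, and every alternative for TBE, were made after the data had been seen. The others were fixed before. Of 130 alternative values of the comparisons, 55 stayed within the counting interval or within 1.5 times a count, and 75 moved. Densities at contig ends and correlations had limits of their own. A reversal was not defined for these values. For single reference sequences 158 of 200 stayed, 41 moved and 1 reversed. No paired analysis was possible because each time point had 1 library. Counting intervals of shares are narrow at this depth, so small shifts count as moved, and the cause of the moves was not tested.

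The 27-nt share at 12, 19, 23 and 30 hr was 76.1%, 75.3%, 79.3% and 77.0% of distinct sequences, 88.9%, 88.6%, 88.1% and 88.0% of reads with a single alignment, 88.6%, 88.3%, 87.6% and 87.5% without mismatch, and 88.8%, 88.6%, 87.9% and 87.8% without the 10 most abundant sequences. The 5' U share was 96.7%, 96.3%, 96.7% and 95.9% of distinct sequences and 98.6%, 98.5%, 98.2% and 98.0% at 26 to 28 nt. With a single alignment it was 98.3% at 23 hr and 98.1% at 30 hr, and without mismatch 98.7% at 12 hr, 98.5% at 19 hr and 98.1% at 30 hr. Contigs with 90% of reads on 1 strand were 0% at 19 hr, 0.00693% at 23 hr and 0.00569% at 30 hr of those counted by distinct sequences. Weighted by reads, the 25-nt pairs were 1.83, 1.73, 1.99 and 1.92 times the median.

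The lowest and highest shares of shared sequences were 41.5% and 51.5% with all reads, 49.3% and 56.0% with at least 2 reads, and 46.6% and 50.7% without mismatch. The TBE ratio was 6.65 with reads of every length and 164 with a single alignment, which rests on 1 read at 12 hr; without mismatch it had no value, as 12 hr had 0 such reads.

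Counts at least 2-fold higher from 12 to 19 hr were 13 with a single alignment, 0 with distinct sequences, 18 with every length, 2 with the median of ratios, 20 at 50 reads, 0 at 1000 reads, 2 with a pseudocount of 5 and 15 without mismatch. Lower ones were 1 with a single alignment, 7 with every length and 5 at 50 reads. From 19 to 23 hr, 33 were higher and 66 lower with a single alignment, 0 higher with distinct sequences, 34 higher and 45 lower at 50 reads, 5 and 3 at 1000 reads, and 57 lower without mismatch. From 23 to 30 hr, higher ones were 1 with every length (neither TBE, at a log2 ratio of 0.16, nor Contig4305.0, at 0.30), 26 at 50 reads, 0 at 1000 reads and 0 without mismatch. From 12 to 30 hr, 1 was higher and 5 lower with distinct sequences, 81 higher and 18 lower with the median of ratios, 196 and 21 at 50 reads, 28 and 3 at 1000 reads, 32 lower with a single alignment and 19 lower without mismatch. The contig ranked number 5 among the falls from 12 to 19 hr reversed to a log2 ratio of 0.14 with a single alignment.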

Other observations

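The selection of contigs in the next paragraph, and the tests of base-call errors, of abundant sequences, of shared reads and of 3' overhangs, were chosen after the results had been seen. The tests of alleles, of GC content and of base composition were written before the values they measure were seen.

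Besides TBE, 17 contigs had a ratio of 27-nt reads at 30 to 12 hr with an interval wholly above 8-fold, when reads were divided over their alignments. They were selected, with TBE, as the 18 reference sequences with at least 50 reads over 12 and 30 hr and an interval of the ratio wholly above 8-fold. Of the 17, 6 had at most 3 reads of a single alignment at 30 hr, and 8 met this selection with such reads alone. Together the 18 held an RPM of 0.670 in 27-nt reads at 12 hr, 15.2 at 19 hr, 21.3 at 23 hr and 61.3 at 30 hr, where the 12 and 30 hr values are those used to select them. Their 21-to-23-nt reads were already 1087 at 12 hr, with 1311 at 19 hr, 1136 at 23 hr and 2459 at 30 hr. Scaled to the 27-nt totals, these counts stood at 35.2, 46.7, 64.5 and 79.6 RPM at the successive times. On the 17 contigs, 917 of 967 22-nt reads started with U at 12 hr (94.8%, interval 93.2 to 96.1), but 226 of 508 at 19 hr, 248 of 498 at 23 hr and 658 of 1162 at 30 hr. The 27-nt reads with a 5' U numbered 17 of 19 at 12 hr, 172 of 430 at 19 hr, 132 of 359 at 23 hr and 1434 of 1891 at 30 hr, or 75.8% at 30 hr (73.8 to 77.7). Only 69 of these 1891 reads were also listed on the TBE sequence. Contig4305.0, the first of them, had 0 27-nt reads at 12 hr and 229 at 30 hr, counted whole, and 154 of its 185 reads at 12 hr were 22 nt long.

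Bases that differed from the reference recurred at 65760 sites on 13331 contigs. Mismatches at read positions 3, 4, 7, 11, 13 and 23 were left out of these counts. Pooled over sites, the alternative base had 26.4% of reads at 12 hr, 29.1% at 19 hr, 30.3% at 23 hr and 30.1% at 30 hr. Across 64209 sites with at least 10 reads in each library, these shares correlated with r = 0.826 between 12 and 19 hr, 0.823 between 23 and 30 hr and 0.700 to 0.764 between the other pairs. Sites are not independent replicates.

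A mismatch was more frequent in 27-nt reads at 23 and 30 hr than at 12 and 19 hr. Whether more reads came from non-reference alleles was not decided. The pooled share of the alternative base at recurrent sites was 1.04 times its 19 hr value at 23 hr. This was under the 1.1 times set for this explanation. But the counts left out the read positions where mismatches rose at 23 hr, so a ratio near 1 was largely given beforehand. The share was also lower at 12 hr, at 26.4%, than at 19 hr (29.1%) and 23 hr (30.3%). Base-call errors at single sequencing cycles remain an untested candidate explanation, because position 4 went from 0.713% at 19 hr to 5.61% at 23 hr. The mean share of mismatches at the other 17 read positions was 1.00 times its 19 hr value at 23 hr. These 17 were what remained after the positions seen to differ, and those without listed mismatches, were left out. That ratio therefore describes the pattern and does not test the explanation. The labels name no sequencing run, and the stage of the cells was not tested as an explanation.

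For the 44 contigs that changed at least 2-fold from 19 to 23 hr, the tables argue against reads shared between contigs, since 42 stayed past 2-fold with reads of a single alignment. After a regression on GC content (r = 0.29 between GC content and log2 ratio over 21017 contigs), 39 of the 43 with a value did so. This does not decide on GC content, since log2 ratios had an SD of 0.203 and the regression could take little from changes of this size. The median GC content was 31.4% for contigs that rose, 29.6% for those that fell and 31.4% for all contigs tested. The tables argue against a few abundant sequences for the contigs that fell, all 24 of which changed at least 1.5-fold with each distinct sequence counted once, but leave this open for those that rose, where 13 of 20 did. A test of unequal change of alleles was void because 3 of the 44 had enough sites, with a median change of 1.19 percentage points. With at least 200 reads over the pair, 0 of 40 changed 2-fold from 12 to 19 hr and 0 of 39 from 23 to 30 hr, while 1 contig under that minimum went from 1.72 to 3.62 RPM from 12 to 19 hr, and the stage of the cells stays open and untested. Those that fell had a median log2 ratio of 0.50 from 23 to 30 hr, a return that an offset shared by 23 and 30 hr would not give alone, but they were chosen by their 23 hr values and each time had 1 library, so the step cannot be told apart from a batch difference between 19 and 23 hr.

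The excess of 25-nt overlaps was not accounted for by the 5' U of the reads alone. Base composition at other read positions was not controlled for. Restricted to sites where a read on the opposite strand would start with U, the occupied share at 25 nt was at least 1.27 times the highest share at 2 to 24 nt in each library. A candidate explanation is that part of the RNAs came from duplexes with 2-nt 3' overhangs. In all 8 combinations of library and length for 26-nt and 28-nt reads, the overlap with the highest count was the read length minus 2, as in 14 of 16 for reads of 20 to 23 nt, where at 12 hr 20-nt and 23-nt reads peaked elsewhere (44 pairs against 41 and 299 against 291). This is a hypothesis found and tested on the same libraries, and the design gave no comparison that tests it further.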
